A study of Mus musculus with 3 samples.

How the data were processed

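Single-cell RNA was measured in 3 libraries of mouse lung, 1 each for the treatments Control, Model and PD00. Per the labels' protocols, the libraries were made with a 3' droplet kit (10x Chromium, version 3 chemistry). The deposited matrices hold counts of UMIs per gene and barcode, whole numbers that the authors had not normalised. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 and STAR on mm10, while per the file headers the matrices were written by cellranger 5.0.0. The matrices list 32285 genes and only barcodes already called as cells, so empty droplets were not available and no correction for free RNA was made. Coordinates are those of GRCm38 in the reference annotation, in which 120 of 120 named genes were found by identifier.

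Cells with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. No barcode lay under 500 UMIs, 281 Control, 79 Model and 24 PD00 barcodes lay under 200 genes, and 76, 187 and 192 were above 20% mitochondrial UMIs. Doublets were scored in each library with the Scrublet function of scanpy. Its own threshold called 451 cells in Control (4.61%) but 1 in Model and 4 in PD00, so a score of 0.2 was used in all libraries, which removed 421, 252 and 274 cells (4.30%, 2.18% and 2.84%). That threshold was chosen after the data were seen. The kept cells held 77245146, 79690635 and 76914274 UMIs, with median mitochondrial shares of 4.55%, 4.91% and 4.98%. All 3 libraries held Xist UMIs (75007, 63023 and 66150) and almost no UMIs of Y-linked genes (5, 3 and 4).

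Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen by their rank of dispersion within each library, and 30 principal components with 20 neighbours were clustered by Leiden at resolution 1, without integration. Clusters were named from fixed marker lists: a mean standardised level of at least 1, at least 3 markers detected in 10% of cells, and 10 leading genes that did not belong mostly to another class. A cluster scoring as ILC2 or NK cells in which T cell receptor complex genes were detected in 40% of cells on average was read as T cells. The lists were fixed in advance, the thresholds were not. After the data were seen, rules were added that a cluster with CD45 (Ptprc) UMIs in at least 40% of its cells takes no structural name, and that a T cell cluster whose leading genes are those of ILC2 is kept apart. The epithelial class pools airway and alveolar types.

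UMIs were summed per library and class with at least 50 cells in both libraries, and scaled to CPM of that sum. Ratios of genes with at least 50 UMIs over both sums have exact conditional-binomial (Clopper-Pearson) 95% intervals, and shares of cells have exact Clopper-Pearson intervals; a count of 0 was set at 3 counts per sum. With 1 library per group no test was possible, and cells were not used as replicates. Ratios of shares have intervals of counting error as well. For each gene list the median log2 ratio of measured members was compared with 10000 random lists of equal size drawn from 20 expression bins, and members at least 1.5-fold higher or lower were counted.

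The main comparisons, the filters, the marker lists, the 31 gene lists (3 members were missing from the matrices), the named-gene rule and the alternatives were fixed before the data were examined. The named genes were the 4 highest and 4 lowest over all kept cells and the highest and lowest in each of the 6 immune classes with the most cells in their smaller library. They were ranked by the interval bound nearest to 1, leaving out mitochondrial, ribosomal protein, haemoglobin, sex-specific and antigen receptor segment genes and unnamed gene models. To these were added 2 to 4 members of each described list and 10 readouts of ovalbumin models. Because several of these genes stood at similar levels in the other classes, up to 4 further genes higher or lower per class were taken from those whose level in the class was at least 3 times the median of the other classes. This addition, the other genes named beside the rule, and the choice of which lists and classes the text describes were made after the values were seen.

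Alternatives were a 10% mitochondrial limit, a minimum of 500 genes, doublets kept, resolutions 0.5 and 2, principal components centred per library, scaling by median of ratios or without mitochondrial, ribosomal protein and haemoglobin genes, minimums of 1 and 200 UMIs, equal weight per class, shares of immune cells, and cells thinned to 500 UMIs. Scrublet's own threshold and sums without the unnamed clusters were chosen after seeing the data. Shares of immune cells counted the named immune classes and cluster 5, and left out the unnamed clusters. The ratios and list percentiles were tested on simulated data, Poisson counts drawn at the depths of these libraries with known ratios. Such counts follow the model that the intervals assume, without UMIs clumped in single cells or genes that vary together. They check the computation, not how intervals and percentiles behave in these data. The 95% interval held the true ratio for 95.4% of genes in T cells, 95.7% in neutrophils and 95.2% over all cells. Of genes set 1.5-fold apart, 90.8%, 68.4% and 89.9% had an interval without 1 in the right direction, and of 200 lists with no shift 7.5%, 3.5% and 4.5% lay outside the central 95% of random lists. The software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.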

Results

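Lung cells of mice aged 3 months were profiled by droplet single-cell RNA sequencing in 3 libraries, whose treatment labels read Control, Model and PD00. The series title names ovalbumin as the inducing agent and PD00 as a peptidomimetic. The labels do not say how many animals went into a library, describe the tissue of all 3 as healthy, and do not say whether the PD00 library also received ovalbumin. The count tables held 10133 barcodes and 83281019 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule) for Control, 11772 barcodes and 81816397 UMIs for Model, and 9851 barcodes and 80288883 UMIs for PD00. After filtering, 9368, 11285 and 9373 cells were kept, with medians of 5231.5, 4048 and 4574 UMIs and 1717.5, 1458 and 1630 genes per cell. Thinned to 500 UMIs per cell, the medians were 333, 313 and 320 genes. Each group had 1 library, so no difference has a replicate check, no test was run, and every 95% interval covers counting error only.

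The kept cells fell into 35 clusters, named by marker genes chosen before the data were examined, and each class name below means cells that look like that type. The named classes were T, natural killer (NK), B and plasma cells, group 2 innate lymphoid cells (ILC2), macrophages, monocytes, neutrophils, eosinophils, dendritic cells, basophils or mast cells, and epithelial, endothelial, fibroblast and mural or mesothelial cells. Cluster 5 carried markers of both T cells and ILC2 and was kept apart, at 0.0961% of Control, 7.49% of Model and 10.4% of PD00 cells. The 4 unnamed clusters held 1.89% of Control, 18.1% of Model and 9.83% of PD00 cells. The rules that set aside cluster 5 and the unnamed cluster 10 were fixed after the data were seen. Cluster 10 held 8.60% of Model cells.

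**Figure D1:**
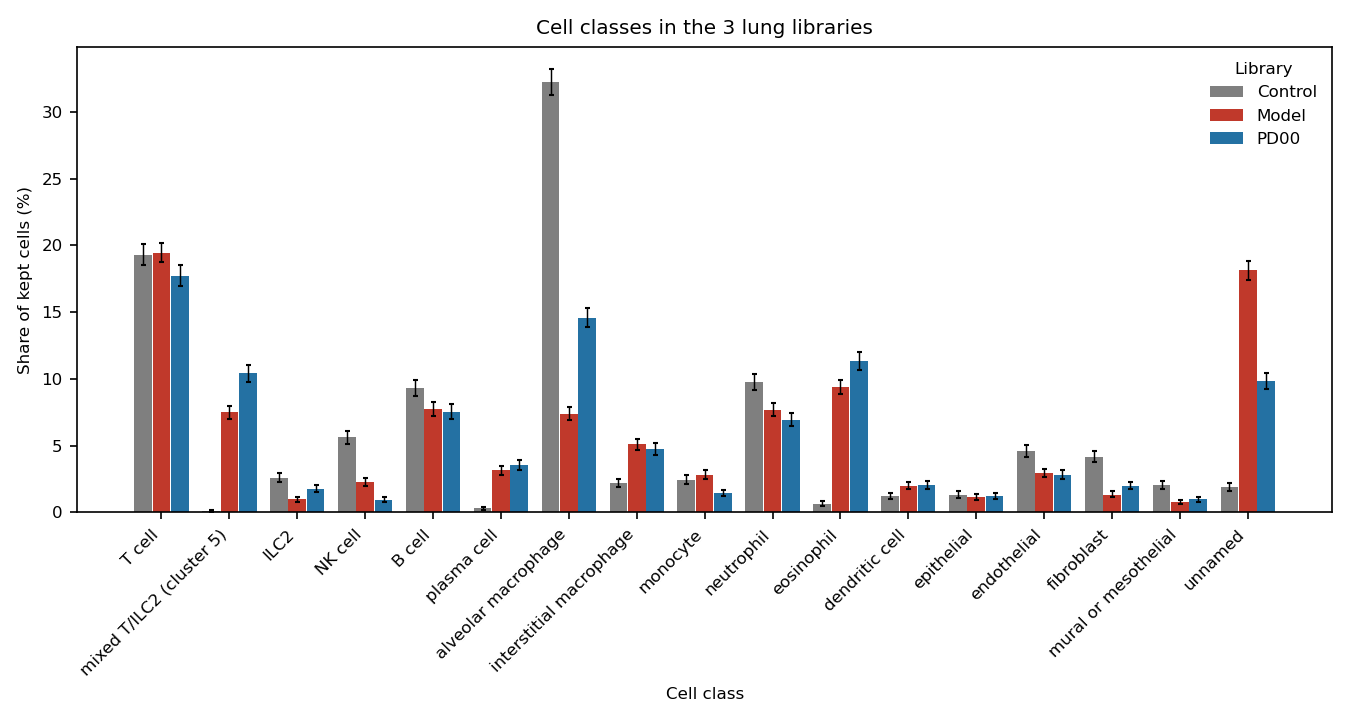
Share of kept cells (%) in each cell class of the Control, Model and PD00 libraries, with exact 95% binomial intervals for counting error; basophils or mast cells and plasmacytoid dendritic cells are left out. Eosinophils made up 0.630% of Control, 9.38% of Model and 11.3% of PD00 cells, and alveolar macrophages 32.2%, 7.35% and 14.6%.

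The first comparison, Model against Control, asks how lung immune cells and their metabolic genes differ in the ovalbumin model. Eosinophils were 14.9-fold higher as a share of cells in Model (9.38% against 0.630%; interval of the ratio 11.4 to 19.7), and plasma cells, which secrete antibody, 10.9-fold higher (3.14% against 0.288%; 7.35 to 16.8). Alveolar macrophages, which clear surfactant and inhaled particles, were 4.38-fold lower (7.35% against 32.2%; 4.06 to 4.74). That class leaves out the unnamed macrophage-like cluster 9, with 4.62% of Model and 0 Control cells. Whether cluster 9 holds alveolar macrophages was not tested. Genes of goblet cell mucus and of type 2 immunity were higher, with the mucus genes concentrated in epithelium. Inflammatory cytokines such as Tnf and Il1a were lower.

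Interstitial macrophages were 2.31-fold higher in Model (5.09% against 2.20%; 1.97 to 2.73) and dendritic cells 1.63-fold higher (1.298 to 2.06). NK cells, which kill infected and transformed cells, were 2.49-fold lower (2.25% against 5.60%; 2.14 to 2.90), and ILC2 other than cluster 5, innate sources of type 2 cytokines, 2.64-fold lower (0.9747% against 2.57%; 2.10 to 3.34). Cluster 5, which also carries ILC2 markers, held 7.49% of Model and 0.0961% of Control cells. The T cell receptor complex gene Cd3e was found in 70.1% of its Model cells, against 81.0% of T cells and 3.64% of ILC2. By this gene most of cluster 5 looks like T cells. Whether it also holds ILC2 was not tested, so the direction for all ILC2 is not settled. Neutrophils were 1.27-fold lower (1.15 to 1.39). T cells other than cluster 5 were 19.5% of Model and 19.3% of Control cells, and with cluster 5 they were 26.9% and 19.4%. Fibroblasts were 3.14-fold lower (2.59 to 3.82) and endothelial cells 1.56-fold lower (1.35 to 1.80), shares that tissue dissociation can set. With a coarser clustering the NK ratio was 0.604 in place of 0.402 and the interstitial macrophage ratio 4.40 in place of 2.31.

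All 22 measured members of the type 2 airway effector list were at least 1.5-fold higher in the sum of all kept Model cells. Their median log2 ratio was 6.06, at percentile 100 among 10000 random lists matched on expression, as a description of these libraries. Clca1 (ENSMUSG00000028255, chromosome 3, 145003817 to 145032776 in GRCm38), a secreted goblet cell protein, had 36384 UMIs in Model and 0 in Control. With the 0 set at 3 UMIs it was 11756-fold higher (lower end of the interval 9560). Chil4 (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507), a chitinase-like protein, had 32761 and 0 UMIs, 10585-fold higher on that footing (lower end 8608). Muc5ac, the gel-forming mucin of goblet cells, had 1318 and 2 UMIs, a ratio of 639 (176 to 5280). The sources were concentrated in epithelial cells, where Clca1 reached 18874 CPM (counts scaled to a sum of 1e6) and the list median was 9.38. The list median lay above 0 in 14 of 14 classes, at 7.43 in alveolar macrophages. Chil4 in interstitial macrophages was at 16.6 CPM beside a median of 18.1 CPM in the other classes, a level that free RNA can give. Rnase2a, a ribonuclease of the eosinophil-associated family, was 3664-fold higher over all cells (2221 to 6547).

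Of the cytokines that drive this response, Il13 was 18.4-fold higher (9.27 against 0.505 CPM; 13.3 to 26.0), Il4 6.77-fold (5.05 to 9.23) and Il5, the eosinophil growth factor, 6.21-fold (4.69 to 8.36). The list of type 2 cytokines and receptors had a median of 2.26, with 9 of 15 members higher and 1 lower. Cluster 5 held 75.0% of the Il13 UMIs of Model, 75.3% of its Il5 UMIs and 53.7% of its Il4 UMIs. In B cells, which should lack Il13, no Model UMI was seen. Chil3, Retnla and Arg1, markers of alternative macrophage activation, were 24.95-fold, 260-fold and 109-fold higher over all cells. Epithelial cells held 34.7% of the Retnla UMIs of Model, so its value over all cells is not one of macrophages alone. The eosinophil-attracting chemokine Ccl24 was 45.05-fold higher (40.5 to 50.2) and Ccl11 2.52-fold (2.32 to 2.73).

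**Figure D2:**
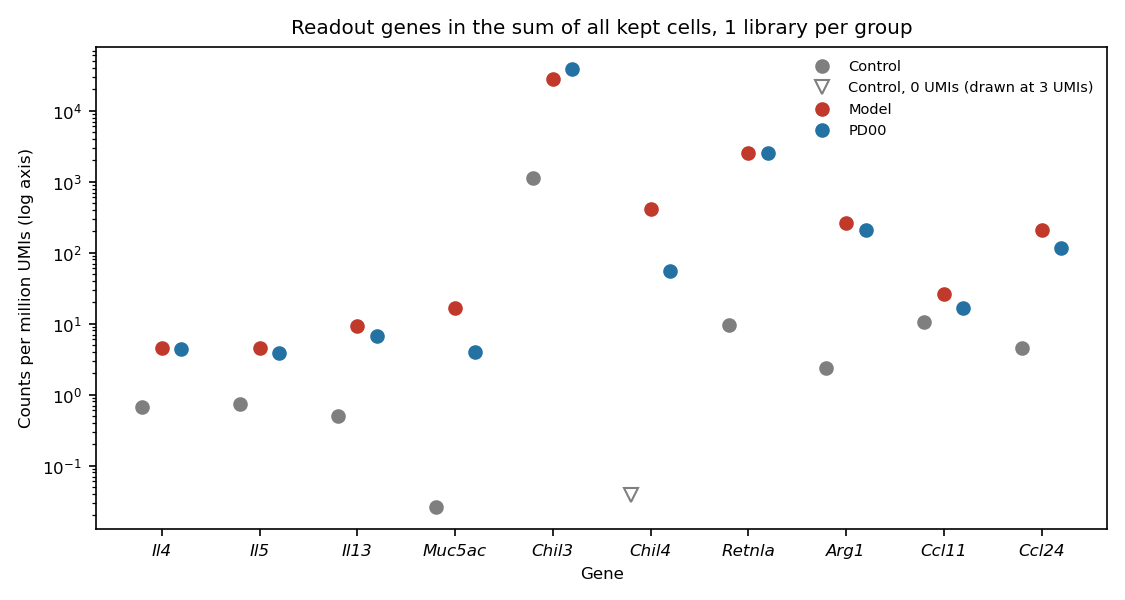
Level of 10 readout genes of ovalbumin models in the sum of all kept cells of each library, in CPM on a log axis, 1 point per library; the open triangle stands for 0 UMIs, drawn at 3 UMIs. Each gene was higher in Model than in Control, and Chil4 and Muc5ac were lower in PD00 than in Model (0.134 and 0.237 of its level).

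Within alveolar macrophages, 12 of 16 members of the alternative activation list were higher and 1 lower, with a median of 4.96. The list median lay above 0 in 14 of 14 classes, with endothelial cells the lowest (0.54), so free RNA can enter these values. Retnla was at 1285 CPM in Model and 0.650 CPM in Control, and Arg1, which diverts arginine from nitric oxide, at 399 and 0.359 CPM. Over all Model cells Retnla stood higher than in this class, at 2523 CPM, and Arg1 lower, at 260 CPM. Ccl17, a chemokine for T helper 2 cells, was 833-fold higher (533 to 1385). Major histocompatibility complex class II genes, which present antigen, were higher in 7 of 8 members (median 2.54), with H2-Eb1 at 741 and 89.7 CPM. The class II median lay above 0 in 12 of 14 classes and was highest in mural or mesothelial cells (3.07). Free RNA can enter these values too. Fbp1, an enzyme of gluconeogenesis, was at 649 and 0.112 CPM. Tnf was at 15.1 against 787 CPM, 52.0-fold lower (46.0 to 59.1), and Fpr1, a receptor for bacterial peptides, 35.8-fold lower (28.0 to 46.6). Cluster 0 held 95.6% of the alveolar macrophages of Control, and cluster 3 held 92.0% of those of Model, so a class value here compares separate clusters, and Tnf, Fbp1 and Chil3 are among the genes that define them. Over all cells Fabp1, a fatty acid binding protein, was 63.5-fold lower (57.7 to 70.0) and Coro6, an actin-binding coronin, 55.7-fold lower (36.6 to 89.2).

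The inflammatory cytokine and chemokine list was lower over all cells, with 14 of 18 members lower, 1 higher, and a median of -1.50 at percentile 0. Tnf was 23.4-fold lower, Il1a 9.20-fold and Ccl3, a chemokine for monocytes, 5.47-fold, while Nos2, the inducible nitric oxide synthase, was 9.89-fold higher (7.45 to 13.4). The median lay below 0 in 13 of 14 classes, with eosinophils (0.17) the exception and interstitial macrophages the lowest (-2.64). In alveolar macrophages 14 of 16 members were lower and 2 higher (median -1.52). In neutrophils, 7 of 12 members were lower, including the neutrophil attractants Cxcl2 (2.85-fold; 2.80 to 2.90) and Cxcl1 (3.75-fold). Neutrophil Il1b was 2.40-fold lower (2.33 to 2.47). Monocytes had 6 of 13 members lower, with a median of -0.49. The immediate-early genes, which tissue handling can induce, were lower too, with a median of -0.52 over all cells and -1.21 in interstitial macrophages, where Atf3 was at 403 against 1383 CPM.

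In interstitial macrophages the alternative activation median was 1.04 (11 of 18 members higher, 2 lower), in a list above 0 in 14 of 14 classes. Pdcd1lg2, an inhibitory ligand of T cells, was 26.8-fold higher there as a point value, with a lower end of the interval of 21.7. T cells had higher T helper and regulatory genes (11 of 17 members, median 0.94), including Gata3, the T helper 2 transcription factor, 3.77-fold (3.36 to 4.24) and Il10, an anti-inflammatory cytokine, 5.42-fold (3.61 to 8.43). Their cell cycle list was higher in 15 of 17 members (median 0.84), with the proliferation marker Mki67 2.35-fold higher (2.18 to 2.52). Cluster 7 held 74.6% of the T cells of Control, and clusters 4, 11 and 14 most of those of Model. NK cells had lower cytotoxicity genes (median -0.50, 3 of 10 members lower, 0 higher), with the granule protease Gzma 1.73-fold lower. Their Il1a was 10.8-fold lower (4.44 to 34.0), at 5.12 against 55.1 CPM, beside medians of 7.02 and 77.2 CPM in the other classes.

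The interferon response list stood at 0.49 over all cells (9 of 22 members higher, 1 lower), 0.71 in neutrophils (9 of 18 members higher, 0 lower) and 0.67 in monocytes (8 of 15 higher, 1 lower). It lay above 0 in 9 of 13 classes and below 0 in 4, with eosinophils the lowest (-0.88). Oasl2 and Zbp1, which sense or answer foreign nucleic acid, were 4.77-fold (3.33 to 6.997) and 4.19-fold (3.23 to 5.51) higher in neutrophils, and Gbp2, an interferon-induced GTPase, 5.36-fold (3.52 to 8.51) in monocytes. The granule genes Camp, Ltf and Ngp, made by immature neutrophils, were 44.4-fold, 41.6-fold and 35.2-fold higher in neutrophils. They are among the leading genes of neutrophil cluster 30, with 77 Model and 5 Control cells. Their UMIs were not split by cluster. In monocytes G0s2, a lipolysis inhibitor, was 5.19-fold lower (3.22 to 8.71), with 34 of its 85 Control UMIs in 1 cell.

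Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), the constant region of antibody class G1, had 582445 UMIs in Model and 10 in Control, 56457-fold higher (30699 to 117733). The immunoglobulin constant list had a median of 3.06, with 11 of 13 members higher. Ighg1 was also the highest gene in each of the 6 immune classes with the most cells in their smaller library. In T cells, which make no antibody, it stood at 730 CPM against a median of 778 CPM in the other classes, a level that free RNA of plasma cells can give. Fabp1, the lowest gene in T and B cells, and Sftpc, a surfactant protein and the lowest gene in neutrophils (12.6-fold; 7.14 to 24.3), are likewise products of other classes. Cartpt and Vip, both neuropeptides, had 878 and 590 UMIs in Control and 0 in Model, and 860 and 585 of these lay in 1 cell each.

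Epithelial cells had higher unfolded protein response genes (median 0.93, 9 of 13 members higher), with Sdf2l1 4.10-fold (2.40 to 7.36) and Xbp1, a driver of secretory cell expansion, 2.04-fold (1.56 to 2.67). Surfactant genes were lower in 8 of 10 members (median -1.17), including Sftpb (6.30-fold) and Sftpc (4.28-fold). The class pools airway and alveolar epithelium, with 128 Model and 123 Control cells. Fibroblasts had 11 of 19 extracellular matrix genes higher and 1 lower (median 0.79), with Postn, a matrix protein induced by interleukin 13, 32.1-fold higher (27.5 to 37.8) and Eln, elastin, 2.63-fold (2.495 to 2.77).

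The metabolic lists differed by less than the type 2 genes and differed between classes. Interstitial macrophages were higher in the tricarboxylic acid cycle (median 0.55, 11 of 24 members higher, 1 lower), glycolysis (0.43, 5 of 20 higher, 2 lower), the pentose phosphate pathway (0.56), nuclear oxidative phosphorylation genes (0.31, 16 of 77 higher, 0 lower) and cholesterol synthesis (0.88, 12 of 17 higher, 0 lower). Among them Pgk1, a glycolytic kinase, was 3.33-fold higher (2.54 to 4.45), Idh1 2.14-fold (1.65 to 2.84) and Hmgcs1, an early enzyme of cholesterol synthesis, 3.80-fold (2.30 to 6.73). Alveolar macrophages had medians above 0 in the tricarboxylic acid cycle (0.30, 6 of 25 members higher, 0 lower), oxidative phosphorylation (0.20, 10 of 77 higher, 1 lower) and cholesterol synthesis (0.31, 5 of 20 higher, 1 lower), with glycolysis at 0.09. Neutrophils were higher in the pentose phosphate pathway, which supplies NADPH (0.95, 4 of 6 members higher, 1 lower), including G6pdx 2.52-fold (1.99 to 3.20) and Tkt 2.63-fold (2.23 to 3.12). They were also higher in fatty acid synthesis and storage (0.67) and glycolysis (0.31). Cluster 30, with 77 Model and 5 Control neutrophils, enters these sums, and its cells held a median of 5947 UMIs against 1974 in cluster 1. Mitochondrially encoded genes had a median above 0 in 13 of 14 classes, including neutrophils (0.83) and alveolar macrophages (0.63). T cells had medians of 0.66 for fatty acid synthesis and storage (10 of 16 members higher, 1 lower) and 0.51 for cholesterol synthesis (8 of 19 higher, 1 lower). Their Dgat1, which completes triglyceride synthesis, was 2.64-fold higher (2.39 to 2.91). Their glycolysis median of 0.35 (2 of 20 higher, 1 lower) lay inside the central 95% of random lists. Oxidative phosphorylation was lower in NK cells (-0.53, 31 of 77 members lower, 0 higher) and, with 8 of 77 members lower, in B cells (-0.25), which lay mostly in cluster 12 in Control and cluster 6 in Model. The median of all genes, for reference, was 0.19 in T cells, 0.13 in neutrophils, -0.18 in alveolar macrophages, 0.42 in epithelial cells, -0.16 in fibroblasts and -0.13 over all cells.

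**Figure D3:**
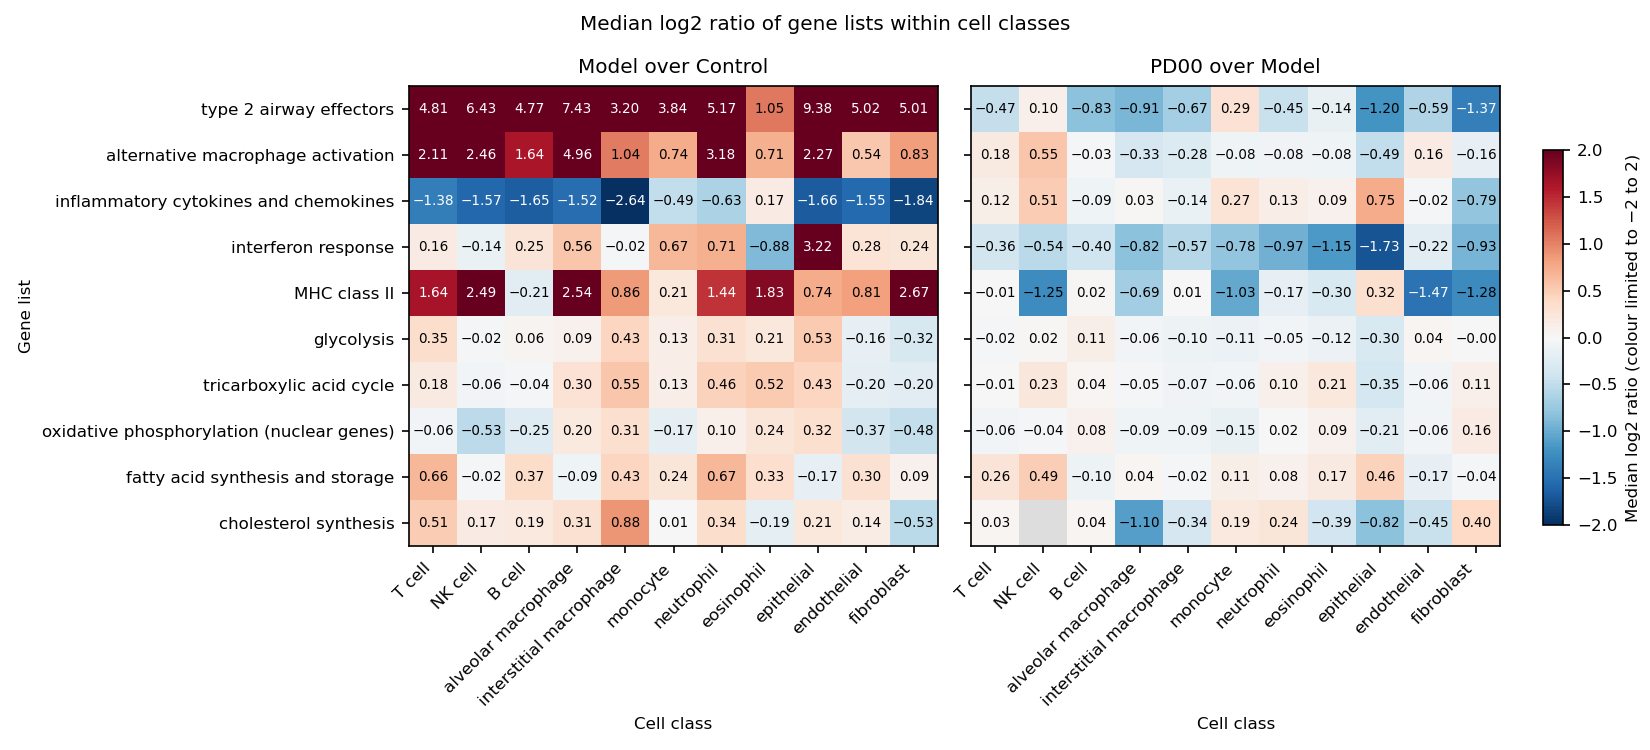
Median log2 ratio of 10 gene lists (vertical axis) within 11 cell classes (horizontal axis), for Model over Control and PD00 over Model; colours are limited to -2 and 2, and grey marks a list with too few measured members. The interferon response list is below 0 in each of these classes for PD00 over Model, from -1.73 in epithelial cells to -0.22 in endothelial cells, while glycolysis and oxidative phosphorylation lie closer to 0 in each.

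The second comparison, PD00 against Model, asks what differs in the library that received PD00. Alveolar macrophages were 1.98-fold higher as a share of cells (14.6% against 7.35%; 1.82 to 2.16) and eosinophils 1.21-fold higher (11.3% against 9.38%; 1.11 to 1.32). The alveolar macrophage share again leaves out cluster 9, at 6.17% of PD00 and 4.62% of Model cells. NK cells were 2.40-fold lower (0.939% against 2.25%; 1.87 to 3.09) and monocytes 1.96-fold lower (1.44% against 2.83%; 1.60 to 2.42). Over all cells, goblet cell genes, interferon response genes and cytotoxicity genes were lower in PD00. The cytokines Il4, Il5 and Il13 differed by less than 1.5-fold over all cells, and the glycolysis and oxidative phosphorylation medians given below lay between -0.12 and 0.09.

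Cluster 5 was 1.39-fold higher in PD00 (1.27 to 1.53), ILC2 1.81-fold (1.41 to 2.32) and fibroblasts 1.501-fold (1.204 to 1.87). Interstitial macrophages (ratio 0.933; 0.823 to 1.06), plasma cells (1.12; 0.963 to 1.31), B cells (0.974; 0.880 to 1.08) and dendritic cells (1.02; 0.835 to 1.24) did not differ detectably at this depth. The unnamed clusters were 1.84-fold lower (1.70 to 1.99), which enters every share of all kept cells. Over the named immune classes and cluster 5 alone, the eosinophil ratio was 1.10 and the alveolar macrophage ratio 1.80. That base leaves out the unnamed clusters 9 and 10, in which 95.4% and 66.4% of cells held a CD45 UMI. It is therefore not a count of all immune cells. Set against Control, PD00 had 2.21-fold fewer alveolar macrophages (2.08 to 2.36), 5.97-fold fewer NK cells (4.75 to 7.57) and an 18.0-fold higher share of eosinophils (13.8 to 23.8). The alveolar macrophages of PD00 lay mostly in cluster 3 (95.5%) and those of Control in cluster 0 (95.6%), so that ratio compares separate clusters.

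The type 2 airway effector list was lower over all cells, with 15 of 22 members lower, 1 higher, and a median of -0.80 at percentile 0. Chil4 was 7.46-fold lower (7.22 to 7.70), Muc5ac 4.23-fold (3.73 to 4.81), and Itln1, a secreted goblet cell lectin, 12.7-fold. Of the Muc5ac UMIs, 1 cell held 414 of 1318 in Model and 1 cell 111 of 301 in PD00. Of the Chil4 UMIs of PD00, 1 cell held 1058 of 4240. The intervals do not cover such clumping. The list median lay below 0 in 14 of 17 groups of cells, at -0.91 in alveolar macrophages. Within epithelial cells 11 of 15 members were lower and 1 higher (median -1.20), with Tff2, a mucus-stabilising peptide, 6.24-fold lower and Muc5ac 4.54-fold lower (3.99 to 5.20). Surfactant genes went the other way there, with 10 of 10 members higher (median 1.15), including Sftpb 3.36-fold (3.05 to 3.70) and Lamp3 3.54-fold (2.98 to 4.22). Bpifa1 (ENSMUSG00000027483, chromosome 2, 154142880 to 154149219), a secreted airway defence protein, had 2 UMIs in PD00 and 6187 in Model, 2986-fold lower (826 to 24660). In Model, 1 cell held 2073 of them. Reg3g, an antimicrobial lectin, had 101 and 6299 UMIs, 60.2-fold lower (49.5 to 74.0). These epithelial values rest on 111 PD00 and 128 Model cells of pooled airway and alveolar types.

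Il4 was at 0.970 of its Model level (0.834 to 1.13), Il5 at 0.840 (0.718 to 0.982) and Il13 at 0.729 (0.650 to 0.817) over all cells, and the median of type 2 cytokines and receptors was -0.09. In cluster 5 Il13 stood at 96.1 CPM in PD00 and 154 CPM in Model. Retnla was at 0.995 of its Model level and Chil3 at 1.39, a gene that alveolar macrophages carry. Within alveolar macrophages the Chil3 ratio was 1.03, Arg1 was 1.93-fold lower (1.86 to 2.003), and Ccl17 3.41-fold lower. Over all cells Arg1 was at 0.796, Ccl24 at 0.571 (0.557 to 0.586) and Ccl11 at 0.622 (0.580 to 0.667) of the Model level. The alternative activation list stood at -0.33 in alveolar macrophages (8 of 17 members lower, 0 higher), led by the lectin Mgl2 (3.60-fold), and at -0.28 in interstitial macrophages (5 of 18 lower, 0 higher).

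Interferon response genes were lower in PD00 in 18 of 22 members over all cells and higher in 0, with a median of -0.79 at percentile 0. The median lay below 0 in 15 of 16 groups of cells, cluster 9 included, with mural or mesothelial cells (0.36) the exception. Irf7, a master regulator of type I interferon, was 2.67-fold lower over all cells. Neutrophils had 12 of 17 members lower (median -0.97), with Oasl2 4.57-fold lower (3.104 to 6.95) and Zbp1 3.79-fold (2.88 to 5.06). Monocytes had 11 of 15 lower (-0.78), with Gbp2 3.96-fold lower, and alveolar macrophages 11 of 20 (-0.82). Eosinophils, with 5 measured members, had 4 lower (-1.15), and their Ifi27l2a, an interferon-induced gene, was 6.21-fold lower (4.42 to 8.94). In epithelial cells 7 of 7 were lower (-1.73), including Isg15, a ubiquitin-like modifier (8.30-fold). That class pools airway and alveolar cells, its surfactant median was 1.15, and the median of all its genes was -0.31. A shift between these cell types can enter the value. T cells (-0.36) and B cells (-0.40) stood closer to 0. With at least 200 UMIs required per gene, the B cell median was 0.00.

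Class II genes were lower in endothelial cells (median -1.47, 7 of 8 members lower), fibroblasts (-1.28, 6 of 6), monocytes (-1.03, 6 of 7) and alveolar macrophages (-0.69, 6 of 8). Their median lay below 0 in 13 of 17 groups of cells and above 0 in 4, with epithelial cells the highest (0.32). Endothelial Ciita, the class II master regulator, was 4.41-fold lower and Cd74, the invariant chain, 2.82-fold lower. Cytotoxicity genes were lower over all cells (median -1.48, 11 of 12 members lower), with Gzma 4.53-fold and Nkg7 3.49-fold lower, beside lower shares of NK cells and of cluster 22 (ratio 0.527; 0.403 to 0.684), T cells led by Ccl5. Their median lay below 0 in 6 of 6 groups of cells, from -2.51 in alveolar macrophages to -0.03 in NK cells. Outside NK cells, these medians do not tell a fall within a class from its make-up or from free RNA of fewer NK cells. The inflammatory list had a median of -0.10, with 3 of 18 members lower and 1 higher. Ccl2 and Ccl7, monocyte attractants, were 2.13-fold and 2.23-fold lower, and Il1a was 1.63-fold higher (1.58 to 1.69). The cell cycle list stood at -0.27 over all cells.

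Cholesterol synthesis in alveolar macrophages had 16 of 20 members lower and 0 higher (median -1.10), with Sqle, the squalene epoxidase, 2.91-fold lower and Idi1 3.14-fold lower. Ch25h, which makes 25-hydroxycholesterol, was 5.50-fold lower there (4.94 to 6.13). The unnamed macrophage-like cluster 9 had 13 of 20 members lower (median -0.85). Glycolysis had medians of -0.02 in T cells, -0.05 in neutrophils, -0.10 in interstitial macrophages, -0.06 in alveolar macrophages and -0.12 in eosinophils. Nuclear oxidative phosphorylation genes had medians of -0.09 in both macrophage classes, -0.04 in NK cells, 0.08 in B cells and 0.09 in eosinophils. These lay at percentile 0 of random lists in both macrophage classes and NK cells, and at or below percentile 2.5 in 10 of 17 groups of cells. The tricarboxylic acid cycle stood at -0.05 in alveolar and -0.07 in interstitial macrophages and at 0.21 in eosinophils. Fatty acid synthesis and storage in T cells had a median of 0.26. Eosinophils had higher heat shock genes (median 0.57, 4 of 8 members higher), including Hsph1 1.95-fold (1.39 to 2.77). The median of all genes lay above 0.1 only in ILC2 (0.10), NK cells (0.13) and cluster 5 (0.11), and in epithelial cells it was -0.31.

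Among single genes, Ighe (ENSMUSG00000087642, chromosome 12, 113269260 to 113273248), the constant region of antibody class E, was 14.2-fold higher in PD00 (9326 against 681 UMIs; 13.1 to 15.4). It was the highest gene in eosinophils, alveolar macrophages and interstitial macrophages too, at 56.3, 8.69 and 38.0 CPM, beside medians of 9.46, 10.5 and 9.46 CPM in the other classes. Eosinophils held a median of 820 UMIs per cell, so little free RNA gives a high CPM there. Such RNA can enter their Ighe value. In interstitial macrophages 117 of the 149 Ighe UMIs lay in 1 cell. The immunoglobulin constant list had a median of -0.09, with 3 of 13 members higher, among them Ighg3 (5.11-fold) and Ighm (4.25-fold), and Ighg2b alone lower (3.38-fold). Foxe1 (ENSMUSG00000070990, chromosome 4, 46343609 to 46346412), a forkhead transcription factor, had 338 UMIs in 274 PD00 cells and 4 in Model, 87.6-fold higher (33.9 to 323). In alveolar macrophages Ear1, a marker of these cells, was 2.49-fold higher (2.39 to 2.59), and Coro6 8.95-fold (3.30 to 34.0).

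Several of the highest and lowest genes came from 1 cell. Elane and Ctsg, granule proteases of neutrophil precursors, were higher in PD00 with 230 of 238 and 154 of 163 UMIs in 1 cell each, placed among T cells by the clustering. Mcpt1 and Mcpt2, mucosal mast cell proteases, had 1576 and 1323 UMIs in Model and 0 in PD00, and 1 cell held 1125 and 817 of them. In B cells Ccl22, a dendritic cell chemokine, was the highest gene with 131 of 169 UMIs in 1 cell, and Ly6a, a stem cell antigen that interferon induces, the lowest (7.15-fold; 4.17 to 13.2). In neutrophils Hist1h2ap, a histone gene, was the highest, with 89 of 99 UMIs in 1 cell. Prg4, a lubricant of joints and serous surfaces, was the lowest in interstitial macrophages, with 113 Model UMIs in 4 cells. Bpifa1 was the lowest in alveolar macrophages, with 62 Model UMIs at 3.68 CPM beside a median of 4.02 CPM in the other classes.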

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

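The doublet test and the test of free RNA shared alike for cluster 10, and all tests of the inflammatory list, were chosen only after the result was seen. An earlier doublet test of cluster 10 was replaced because it could not separate doublets from epithelial RNA of any source. An earlier test of free RNA there was replaced because it used the leading genes of the cluster, and the free RNA test of the inflammatory list was split by class after its pooled values were seen.

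Several clusters without a class name made up more of Model than of Control, where they were nearly absent. Cluster 9, led by the macrophage genes Gpnmb, Arg1 and Trem2, made up 4.62% of Model and 6.17% of PD00 cells and 0 of 9368 Control cells. Cluster 15, led by Rnase2a, Mmp12 and Trem2, made up 4.19% of Model, 2.81% of PD00 and 0.0107% of Control cells. Its cells had a median of 693 UMIs, the lowest of all clusters, and 7.63% mitochondrial UMIs, and 30.5% of them held a CD45 UMI, so droplets with little RNA are not excluded. Cluster 10 made up 8.60% of Model and 0.0107% of Control cells, and held 10 PD00 cells.

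Cluster 10 was led by the goblet cell genes Itln1, Clca1, Bpifb1 and Chil4 beside the macrophage genes Mmp12 and Ccl24. The immunoglobulin genes Igha and Ighg1 were among its leading genes too. The epithelial part of its RNA depended on the genes used, at 10.6% by summed junction genes, 5.39% by Clca1 and a median of 3.64% over 26 airway epithelial genes. Doublets are argued against by the highest of these, where whole epithelial cells would need at least 20%, and by a median of 2287 UMIs against 6794 in epithelial cells. Free RNA shared alike by all droplets is argued against by 22 airway epithelial genes that did not lead the cluster. Their UMIs per cell stood at a median of 10.3 times the immune classes, and 21 of the 22 lay above 3 times. For the epithelial genes, a candidate explanation is airway epithelial RNA taken up by some immune droplets. Of the 26 airway epithelial genes, 92.3% (24 of 26) implied a share within 3-fold of their median share of 3.64%. Doublets and free RNA shared alike would keep these ratios too. This value therefore does not set the candidate explanation apart from them. The explanation does not cover Igha and Ighg1, and RNA of other sources was not tested. A difference of treatment group stays open and untested, because the cluster lies in 1 library.

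Interferon response genes were lower in PD00 than in Model in most classes. In neutrophils the drop was 7.59 times the median drop over 17 groups of cells. That ratio alone does not decide, since free RNA weighs more in CPM where cells hold few UMIs. Eosinophils held a median of 820 UMIs per cell, against 1974 in neutrophil cluster 1. Free RNA shared alike would therefore lower eosinophils more, but their drop was smaller. This argues against free RNA alone in neutrophils, in a comparison made after the values were seen. Monocytes dropped by 1485 CPM, also above the eosinophil drop and the median of 284 CPM. For groups with a drop near the median the test cannot decide, since free RNA could bring a drop of that size. A shift in the make-up of clusters within classes is argued against, since 96% of finer clusters (24 of 25) had a median below 0. Treatment with PD00 and a difference between single animals or libraries were not tested and stay open.

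Inflammatory cytokines were lower in Model than in Control in most classes. In 9 classes (lymphoid, structural and eosinophils), free RNA of alveolar macrophages may account for much of the Control level, since the members stood at a median of 1.31 times the level such RNA would bring. The ratio ran from 0.931 to 2.66, with ILC2 the highest and eosinophils, whose list was not lower, at 2.39. In neutrophils, monocytes and dendritic cells it is argued against, since the ratio was 7.49 in the lowest of them and 22.1 in the highest. Neither macrophage class was part of this test. Handling stress of the Control cells cannot be told apart from a difference of treatment, since the immediate-early list was also in the lowest 2.5% in 5 of 12 classes, which neither excludes nor requires it. The treatment group stays open and untested.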

How the results depend on the processing

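Scrublet's own threshold and sums without the unnamed clusters were chosen only after the data were seen. No paired analysis was possible because each group had 1 library. Of 258 values of class share ratios under the alternatives, 232 stayed within the counting interval, 26 moved beyond it and 0 reversed. Of 1148 values of list medians 990 stayed, 154 moved and 4 reversed, and of 6445 values of gene ratios 6042 stayed, 393 moved and 10 reversed. Over every list in every class, where 7256 values were computed, 60 reversed. Thinning to 500 UMIs lowers genes per cell by construction. Control stayed the highest and Model the lowest, with medians of 333 genes in Control, 313 in Model and 320 in PD00. The cause was not tested for any other value here.

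At resolution 0.5 the Model over Control share ratio was 0.604 for NK cells (0.402 as reported) and 4.40 for interstitial macrophages (2.31 as reported), and at resolution 2 the latter was 2.83. With centred components the NK ratio was 0.603. The alveolar macrophage ratio of 0.228 was 0.275 with at least 500 genes, 0.175 with at most 10% mitochondrial UMIs and 0.259 over immune cells. For PD00 over Model the alveolar macrophage ratio of 1.98 was 2.23 with at most 10% mitochondrial UMIs and 1.80 over immune cells, where the eosinophil ratio was 1.10. The NK and monocyte ratios of PD00 over Model stayed within their intervals under each alternative run.

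With classes weighted equally, the type 2 effector median was 5.35 for Model over Control and -0.71 for PD00 over Model, the inflammatory median -1.20 and the interferon median of PD00 over Model -0.60. Under that weighting 3 medians reversed, to 0.17 for eicosanoids and 0.29 for epithelial junctions (Model over Control) and 0.17 for complement (PD00 over Model). Median-of-ratios scaling gave -1.36 for the inflammatory list. At most 10% mitochondrial UMIs gave -0.75 for type 2 effectors and -1.22 for cholesterol synthesis in alveolar macrophages (PD00 over Model). With at least 200 UMIs the interferon median in B cells was 0.00425.

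The other reversals were single log2 ratios of PD00 over Model. Rbp4 in interstitial macrophages, 2.99 with the settings used, was -0.90 at resolution 0.5. Chil3 in interstitial macrophages, -0.08 as reported, was 0.41 at resolution 0.5, 0.00307 at resolution 2, 0.0878 with at least 500 genes, 0.32 with at most 10% mitochondrial UMIs, 0.17 with centred components, 0.36 with doublets kept and 0.43 with Scrublet's own threshold. Chil3 in neutrophils, -0.08 as reported, was 0.13 with doublets kept and 0.0590 with that threshold. Cluster 9 has no value where cells were clustered again, since cluster numbers then differ. Depth limits genes in small classes, and differences between animals were not measured at any depth.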

Other observations

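No test in this part was chosen after its result was seen, since values alone are given, but the lists below were picked for description after their medians were seen. Over all kept cells, 6 of 12 complement genes were higher in Model than in Control and 4 lower (median 0.62). C1qc, a subunit of the first complement component, was 5.91-fold higher (5.67 to 6.16), and C3ar1, the receptor of a complement fragment, 8.78-fold (7.95 to 9.70). In PD00 the complement median was -0.12 against Model, with C1qb 1.62-fold lower and C2 2.05-fold higher (1.83 to 2.299). Of the glutathione and antioxidant genes, 9 of 24 were lower in Model and 0 higher (median -0.40), including Gsta3 (4.28-fold) and Hmox1, which degrades haem (2.61-fold). In PD00 their median was 0.05 against Model, and Gsta3 was 2.56-fold higher (2.22 to 2.95).

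Eicosanoid genes had a median of -0.31 over all cells in Model against Control, with 7 of 15 members lower and 3 higher. By class the direction turned, with the median above 0 in 9 of 12 classes and below 0 in 3. With classes weighted equally it was 0.17. Values in this paragraph are over all kept cells and carry their make-up, with alveolar macrophages at 32.2% of Control and 7.35% of Model cells. Ltc4s, which makes leukotriene C4, was 7.58-fold lower (7.18 to 8.001), and Alox15, a lipoxygenase of eosinophils and macrophages, 23.5-fold higher (18.7 to 29.9). In PD00 the median was 0.00291, and Ltc4s was 1.85-fold higher than in Model (1.73 to 1.97). Fatty acid oxidation had medians of -0.28 and 0.15 in these comparisons, with Cpt1a, which brings fatty acids into mitochondria, 1.74-fold lower in Model than in Control. The median of arginine and polyamine genes was 0.13 in Model against Control and -0.00409 in PD00 against Model, that of tryptophan and kynurenine genes 0.36 and -0.20, and that of glutamine and serine genes 0.27 and -0.02. Il4i1, an amino acid oxidase, was 12.4-fold higher in Model (9.87 to 15.7) and 1.71-fold lower in PD00 than in Model. Phgdh, the first enzyme of serine synthesis, was 3.39-fold lower in Model than in Control. Epithelial junction genes had medians of -0.34 and -0.27. For Model against Control 6 of 15 members were higher and 6 lower, and with classes weighted equally the median was 0.29. Cdh1, the adhesion protein of epithelium and of some macrophages, was 4.40-fold higher in Model.

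In 8 classes (T and B cells, both macrophage classes, neutrophils, monocytes, endothelial cells and fibroblasts), 7 genes had an interval above 2-fold for Model over Control in each class. Among these Chil3 in T cells was at 2277 CPM in Model, beside a median of 2630 CPM in the other classes, so the rule does not tell the RNA of a class from free RNA. Cxcl2 was lower in each class, at 0.154 to 0.376 of the Control level. No gene met this rule for PD00 against Model. The unnamed cluster 25, led by haemoglobin genes, held 175 Control, 80 Model and 70 PD00 cells.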
